A study of Mus musculus with 6 samples.

How the data were processed

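The 6 libraries were of total RNA from sorted CD8+ T cells, 3 WT and 3 Id2 knockout, made with a standard Illumina protocol per the labels' protocols. The submitters' processing notes name CASAVA, Bowtie2, RSEM and the mouse build mm10, with no version. The deposited tables give for each gene an expected count, the number of reads that RSEM assigns after dividing those that match several genes, and the FPKM value, which divides by transcript length and library size, per the file headers. About 25% of the expected counts in a library were not whole numbers. The lowest FPKM listed was 0.01, and a gene missing from a library's table was taken as 0. Whether counting used strand is not given in the sources used here, so overlapping antisense genes cannot be separated.

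The tables were joined by NCBI gene number. Of 16749 numbers listed in at least 1 library, 16707 had a symbol in the RefSeq table of the mm10 assembly and 42 had none. Each library listed between 14298 and 14842 genes, and Actb took the largest share of the counts, between 0.99% and 1.63%. Expected counts were rounded to whole numbers, scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, on the 10890 genes with an FPKM of at least 1 in at least 3 of the 6 libraries. The filter left out 5859 genes. The design written before the data were examined could be read as placing that filter only in the branch for tables without counts, and an unfiltered fit was therefore run too. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The biological coefficient of variation was 0.156. The standard error of a log2 fold change was its size divided by the square root of the F statistic. Counting intervals of genes with 1 to 3 counts in a group are exact (Clopper-Pearson) and cover counting error only.

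Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 26 lists with at least 2 tested members. There were 18 gene lists and 9 marker lists of other cell types, all fixed before the data were examined. None of the 13 camera calls held with an estimated correlation. Fry, which asks whether the genes of a list move on balance one way without comparing them with other genes, was run as a further alternative. Some genes stand in several lists, such as Gzma among effector and NK cell genes, Prdm1 among effector and plasma cell genes and Bst2 among interferon and dendritic cell genes. Blk stands among B cell and gamma delta T cell markers.

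The genes named were chosen by a rule: Id2, the other Id and E protein genes, and the 12 largest rises and falls past the threshold with a mean of at least 5 FPKM in the higher group and no overlap between groups. Unnamed gene models, receptor segments and sex-linked marker genes were left out of these. To them were added up to 4 members of each gene list with the smallest p (up to 2 per direction where a list went both ways) and the 3 most abundant members of each marker list. E2f1, Prf1, Cd8a, Itgax, Zbtb46, Prdm1, Jchain, Ifng, Fos and Jun were named outside the rule, after their values were seen. So were members of the gene families and small nuclear RNAs under other observations that the rule did not take. Some genes that the rule takes are not reported here.

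On simulated counts with 200 changed genes among 10890, edgeR recovered 84% of the genes changed 2-fold and 97% of those changed 4-fold, with 16 false calls among 197. DESeq2 made 30 false calls among 211, and limma 13 among 192. None of 100 simulated lists without a shift was called by camera, but those lists held independent genes. No libraries of a group were duplicates, since their counts differed by a chi-square of 5.42 to 17.5 per degree of freedom.

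Alternatives were DESeq2 1.42.0, its size factors in edgeR, limma on log2(FPKM + 1) with pseudocounts of 0.5 and 0.1, quantile normalization or library weights, no filter, an FPKM minimum of 5, the replicate number as a block, a log2 fold change minimum of 0.5, removal of the 50 most abundant genes, and each library left out. Tables were joined with pandas 2.3.3 in Python 3.11.15 and drawn with matplotlib 3.10.9.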

Results

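RNA was sequenced from CD8+ T cells sorted by flow cytometry from the iLN (the submitters' abbreviation for the tissue) of C57BL/6 mice. The series title states that the mice bore tumors and had received oxaliplatin, a platinum drug that damages DNA. Of the 6 libraries, 3 came from mice with floxed Id2 and no Cre, called WT here, and 3 came from mice that also carried Cd4-Cre, called knockout. Id2 is an inhibitor of the E protein transcription factors, which it binds and keeps off DNA. The WT libraries held 8383034, 8495123 and 8307284 expected counts and the knockout libraries 7990095, 7699181 and 7751207. Nothing in the labels says which animals the samples of a group came from, so the p-values measure the spread between these samples, which may be technical. Levels are mean FPKM ± SD over the 3 libraries of a group, and fold changes are knockout over WT.

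The comparison asks how CD8+ T cells differ between these genotypes. Cre was present only in the knockout group, so an effect of Cre itself cannot be told apart from loss of Id2. Id2 itself was the gene with the largest fall among those that the naming rule took. Its level was 222 ± 129 FPKM in WT and 2.14 ± 0.485 in knockout, a log2 fold change of -6.72 (SE 0.474, adjusted p = 8.47e-05, edgeR). The WT libraries held 370.98, 146.76 and 149.01 FPKM and the knockout libraries 1.67, 2.64 and 2.12. Without WT replicate 1 the log2 fold change was -6.08. The gene lies on mm10 chromosome 12 from 25093799 to 25096092. In its GENCODE transcript Id2-201, exon 1 and exon 2 hold coding sequence and exon 3 is 3' untranslated. Which exons are floxed is not given in the labels, and reads from exons outside the deleted part would still count. Its relative Id3 rose from 78.2 ± 39.8 to 286 ± 40.8 FPKM (log2 fold change 1.84, SE 0.299, adjusted p = 0.00354). The other members tested did not pass. Tcf3, which encodes the E protein E2A, had a log2 fold change of -0.58 (adjusted p = 0.0695), Tcf12 one of 0.4 (adjusted p = 0.177) and Id1 one of 1.11 (adjusted p = 0.221). The median of the 5 tested members was 0.4 and their mean -0.79, and the list did not pass (camera adjusted p = 0.965). Adjusted over the list alone, 1 member was higher and 2 lower, which is also the count without knockout replicate 1.

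**Figure D1:**
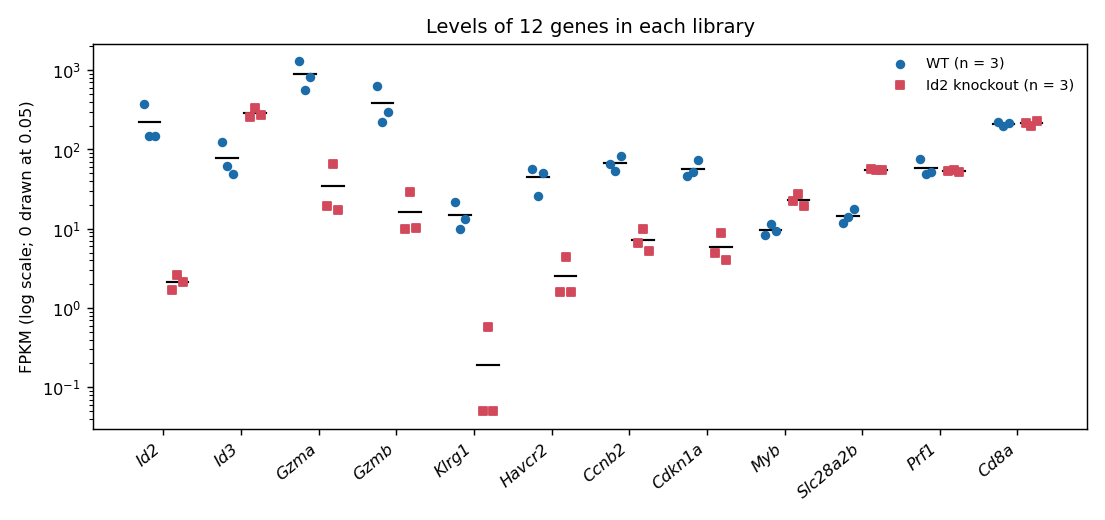
FPKM on a log axis of 12 genes in each of the 3 WT (circles) and 3 knockout (squares) libraries, with bars at the group means and values of 0 drawn at 0.05. Id2, Gzma, Gzmb, Klrg1, Havcr2, Ccnb2 and Cdkn1a are lower in every knockout library than in any WT library, Id3, Myb and Slc28a2b are higher, and Cd8a has a mean of 212 in WT and 214 in knockout.

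Across the 10890 genes tested, 342 were higher and 955 lower in the knockout libraries, 1297 in all. The cells kept their CD8 transcripts at a like level, with Cd8a at 212 ± 10.9 and 214 ± 17.8 FPKM (adjusted p = 0.999). The 12 largest falls that met the naming rule were, after Id2, in Klrg1, Clec12a, Cryab, Mt2, Anxa1, Batf3, Gzma, Adam8, Gzmb, Lgals3 and Niban2. Klrg1, a receptor of terminally differentiated effector cells, fell from 15 ± 6.18 to 0.19 ± 0.329 FPKM, with 6 counts in the knockout libraries together. The granzyme genes Gzma and Gzmb, which encode proteases of cytotoxic granules, fell from 893 ± 369 to 34.2 ± 27.4 and from 385 ± 221 to 16.4 ± 11 FPKM. Anxa1 fell 29.8-fold, Batf3 29.7-fold, Adam8 25.4-fold, Lgals3 23.9-fold and Niban2 22-fold. Clec12a fell from 5.85 ± 3.54 to 0.0767 ± 0.0862 FPKM. Cryab had 123 counts in WT and 2 in knockout, a ratio of 57.2 with an exact 95% counting interval of 15.5 to 478. The metallothionein gene Mt2 had 129 and 3 counts, a ratio of 40 (13.4 to 197). Several falls changed in size with 1 library and kept their call. Without knockout replicate 2, where Klrg1 had no counts left in knockout, the log2 fold changes were -5.61 for Gzma (-4.75 in all libraries), -5.27 for Gzmb (-4.6), -5.51 for Lgals3 (-4.58), -5.9 for Adam8 (-4.67) and -5.69 for Niban2 (-4.46). Gzmb stood at -3.97 without WT replicate 1, Cryab at -4.95 (-5.6) without WT replicate 2, Batf3 at -6.42 (-4.89) without knockout replicate 3, and Clec12a at -7.35 (-6.13) and Mt2 at -6.01 (-5.17) without knockout replicate 1.

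The 12 largest rises that met the naming rule were smaller, between 1.4 and 2.9 on the log2 scale. The rule left out unnamed gene models, among them 5830411N06Rik, which rose by 2.81. Igsf23 rose from 1.06 ± 0.687 to 8.11 ± 4.49 FPKM (log2 fold change 2.9, and 3.49 without WT replicate 2). The nucleoside transporter gene Slc28a2b rose from 14.5 ± 2.94 to 55.4 ± 0.541, the neutral amino acid transporter gene Slc6a19 from 10.3 ± 1.44 to 36 ± 2.4 and the beta tubulin gene Tubb2a from 44.7 ± 3.12 to 127 ± 12 FPKM. Ifngas1, a noncoding RNA gene beside Ifng, rose 3.24-fold, while Ifng itself fell (log2 fold change -1.86, adjusted p = 0.00383, edgeR). Klra23, a Ly49 receptor gene, rose 3.1-fold. The calls of 5 further genes ended in some fits of 5 libraries. H4c1 (log2 fold change 2.02) lost its call without knockout replicate 3 or without WT replicate 1, 2 or 3 (adjusted p = 0.17, 0.0896, 0.0793 and 0.137), with log2 fold changes of 1.37, 1.96, 2.21 and 1.92. H2ac6 (1.76) lost it without knockout replicate 1 or 3 or WT replicate 3 (0.0605, 0.0735 and 0.069, at 1.59, 1.66 and 1.76). Erdr1 (1.61) lost it without any of WT replicates 1 to 3 (0.1, 0.111 and 0.117, at 1.52, 1.61 and 1.72), and its knockout level rested on replicate 2 (65.73, 271.88 and 78.4 FPKM), without which its log2 fold change was 0.71 (adjusted p = 0.0151). The call was lost for Fam240a (1.57) and Rnu3b1 (1.4) without knockout replicate 3 (0.0756 and 0.0787) or WT replicate 3 (0.0761 and 0.0573). Without these, Fam240a stood at 1.45 and 1.43 and Rnu3b1 at 1.12 and 1.14. Rnu3b1, the histone, Ly49 and Slc28a2b genes have near-identical relatives, so their share of reads is uncertain.

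The number of genes past the threshold depended on single libraries. It was 685 without WT replicate 3 and 601 without knockout replicate 3, and the number of higher genes was 121 and 84 there, 210 without WT replicate 2 and 213 without knockout replicate 1.

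Most of the listed genes of cytotoxic effector cells fell. Of 39 tested, 28 fell and none rose (31 and 2 when adjusted over the list alone), with a median log2 fold change of -1.86. The activating receptor gene Klrk1 fell from 61.8 ± 8.37 to 7.77 ± 0.582 FPKM, the lectin gene Klrc1 from 187 ± 32.6 to 19.1 ± 6.34, Lgals1 from 1160 ± 248 to 151 ± 24.2 and Anxa2 from 399 ± 94.6 to 54.6 ± 13.9. The perforin gene Prf1 stood at 58.9 ± 15.4 and 53.6 ± 1.04 FPKM (adjusted p = 0.604). The list differed from other genes by camera with a preset correlation (adjusted p = 1.66e-21) and not with an estimated one (adjusted p = 0.343 with an estimated correlation). Transcripts of B cells varied beside these changes: the summed FPKM of the B cell markers was 962, 3210 and 3760 in WT and 705, 3050 and 635 in knockout. With the B cell marker level as a covariate, a choice made after seeing the data, 30 effector genes fell. Without knockout replicate 2, 1 rose.

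Cell cycle genes fell almost without exception, 41 of 42 tested, with a median of -2.15 (41 also when adjusted over the list alone). The mitotic cyclin gene Ccnb2 fell from 66.9 ± 14.8 to 7.24 ± 2.33 FPKM, Aurkb, which encodes a mitotic kinase, from 27.6 ± 5.84 to 2.7 ± 1.16, Stmn1 from 277 ± 45.4 to 61.7 ± 12.2 and Hmgb2 from 378 ± 44.6 to 119 ± 17.5. E2f1 was the member that did not pass (log2 fold change 0.23, adjusted p = 0.363). For the list, camera gave an adjusted p of 2.62e-38, and of 0.343 with an estimated correlation. With the B cell covariate 41 members fell.

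Genes of naive and memory T cells moved up, 12 of 31 tested (16 when adjusted over the list alone), with a median of 0.45. Besides Id3, the transcription factor genes Myb and Bach2 rose from 9.68 ± 1.58 to 23.1 ± 4.09 and from 8.42 ± 0.608 to 14.1 ± 0.902 FPKM, and Nsg2 from 36.9 ± 0.713 to 58.7 ± 2.74. By camera the adjusted p was 2.11e-09, and 0.343 with an estimated correlation. The count fell to 5 without WT replicate 3, 5 without knockout replicate 1 and 4 without knockout replicate 3. With the B cell covariate it was 8.

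Glycolysis genes were lower, with 13 of 21 past the threshold, 1 higher and a median of -0.51 (14 and 1 when adjusted over the list alone). Tpi1 fell from 152 ± 36.9 to 57 ± 8.02 FPKM and the hexokinase gene Hk2 from 3.88 ± 0.221 to 1.41 ± 0.348. Pdk1, which encodes an inhibitory kinase of pyruvate dehydrogenase, was the member that rose (log2 fold change 0.58), and its call ended without knockout replicate 1 (adjusted p = 0.0556), knockout replicate 3 (0.055) or WT replicate 3 (0.063). Of 32 oxidative phosphorylation genes 4 fell, the respiratory chain genes Cox5a (217 ± 9.81 to 129 ± 8.54 FPKM), Ndufa4, Sdhb and Ndufb9 (6 when adjusted over the list alone, median -0.21). That count was 2 without WT replicate 3, where Sdhb (adjusted p = 0.059) and Ndufb9 (0.0623) lost their calls, or without knockout replicate 3 (0.0711 and 0.0947), and Ndufb9 lost its call without WT replicate 1 (0.0509). The camera adjusted p was 1.6e-07 for glycolysis and 8.95e-06 for oxidative phosphorylation, against adjusted p = 0.343 and 0.379 with an estimated correlation.

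Inhibitory receptor and exhaustion genes went both ways, with 3 of 20 higher and 4 lower, the same counts when adjusted over the list alone, and a median of -0.03 (camera adjusted p = 0.886). The inhibitory receptor genes Havcr2 (TIM-3) and Pdcd1 (PD-1) fell from 44.3 ± 16.5 to 2.53 ± 1.64 and from 65.2 ± 27.4 to 12.8 ± 2.49 FPKM, and Havcr2 had a log2 fold change of -4.16, or -4.79 without knockout replicate 2. Tox, a transcription factor gene, rose from 37.3 ± 2.77 to 56.1 ± 7.74 FPKM, a call that ended without knockout replicate 1 (adjusted p = 0.0603), knockout replicate 3 (0.0781) or WT replicate 3 (0.079). Of 31 activation genes 4 fell, also when adjusted over the list alone, among them the receptor genes Il2ra (17 ± 3.66 to 4.24 ± 0.434 FPKM) and Tnfrsf9 (62.3 ± 18.7 to 22 ± 4.32). Without knockout replicate 1 or 3, the number of higher inhibitory receptor genes was 1 or 0. The number of activation genes that fell was 2 without knockout replicate 3, and 8 rose without WT replicate 1 and 1 without knockout replicate 2. The median of the activation list was 0.06, its mean -0.1 and its camera adjusted p 0.963.

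Among 36 p53 target and DNA damage genes 2 were higher and 6 lower (4 and 9 when adjusted over the list alone, median -0.1, camera adjusted p = 0.393). Cdkn1a, which encodes the cell cycle inhibitor p21, fell from 57.2 ± 15.2 to 5.94 ± 2.53 FPKM. No member of that list was higher by edgeR without WT replicate 2 or 3 or knockout replicate 1 or 3. Of 13 BCL2 family genes 1 was higher and 3 lower (1 and 5 over the list alone, camera adjusted p = 0.213). The higher one, Bcl2, lost its call without WT replicate 1 (0.0676) or 3 (0.0631) or knockout replicate 1 (0.0544), 2 (0.0563) or 3 (0.0608), which left 0 higher. Bcl2a1d and Bcl2a1b, close copies whose reads are hard to divide, fell 2.73-fold and 1.59-fold.

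Type I interferon response genes had a median of -0.38, and 3 of 32 fell (8 when adjusted over the list alone). Cmpk2 fell from 7.44 ± 0.577 to 3.37 ± 0.655 FPKM. The number that fell was 19 without knockout replicate 2 and 1 without knockout replicate 1 or 3. The camera adjusted p was 0.000574 and 0.629 with an estimated correlation. Chaperone genes had 7 of 22 members lower (8 over the list alone, median -0.17). Pdia6 fell from 114 ± 3.78 to 57.4 ± 6.98 and Hsp90b1 from 243 ± 13 to 148 ± 7.49 FPKM. The number that fell was 4 without knockout replicate 3, and 3 members rose without WT replicate 1. The camera adjusted p was 0.0102, against 0.667 without WT replicate 1 and adjusted p = 0.68 with an estimated correlation.

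Of 23 chemokine receptor and homing genes 1 was higher and 5 lower (4 and 5 over the list alone, camera adjusted p = 0.376), with Cxcr6 going from 162 ± 59.4 to 28.2 ± 1.71 and Ccr2 from 30.5 ± 10.6 to 4.82 ± 2.16 FPKM. Among 32 cytokine signalling genes 3 were higher and 6 lower (6 and 6 over the list alone, camera adjusted p = 0.508). Il4ra rose from 136 ± 11.4 to 217 ± 36.9 FPKM, and Cish, a feedback inhibitor of cytokine receptors, fell from 13.1 ± 1.62 to 4.66 ± 0.875. The median of that list was 0.18 and its mean -0.35. Of 14 genes regulated by E proteins 1 was higher and 1 lower, also over the list alone (camera adjusted p = 0.0562), and of 10 follicular helper and innate-like genes likewise 1 and 1 (camera adjusted p = 0.834). T cell receptor signalling genes had a median of 0.19 with 1 of 31 higher and 1 lower, and 40 ribosomal protein genes a median of 0.07 with 0 past the threshold by edgeR, DESeq2 or limma and 0 at an unadjusted p under 0.05. Adjusted over the list alone, 1 and 0 passed. Their camera adjusted p of 0.0185 and 0.0417 became adjusted p = 0.68 and 0.706 with an estimated correlation. Without knockout replicate 2, 7 T cell receptor genes, 6 cytokine genes and 3 homing genes were higher, and without WT replicate 2 or knockout replicate 1 or 3 only 1 cytokine gene was. E protein-regulated genes had 2 members higher without WT replicate 1 or 2 or knockout replicate 2, none lower without WT replicate 2, and 0 higher and 0 lower by edgeR without WT replicate 3 or knockout replicate 1 or 3. Homing genes had 2 higher without WT replicate 1. The higher homing and follicular helper gene of the full fit, Cxcr5, lost its call without WT replicate 3 (0.0549), knockout replicate 1 (0.0568) or knockout replicate 3 (0.0607), which left 0 higher in both lists. Follicular helper genes had 0 lower without WT replicate 1 or knockout replicate 1, 2 or 3. Of the T cell receptor genes, 0 were lower in any fit without 1 library, where the adjusted p of Thy1 was 0.123, 0.0562 and 0.1 without WT replicates 1 to 3 and 0.0889, 0.0686 and 0.144 without knockout replicates 1 to 3. Without WT replicate 3, 0 were higher, as Cblb lost its call (0.0632). The T cell receptor call ended without WT replicate 3 (0.0739), knockout replicate 1 (0.125) or knockout replicate 3 (0.0768), and the ribosomal call without WT replicate 3 (0.159) or knockout replicate 3 (0.169).

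**Figure D2:**
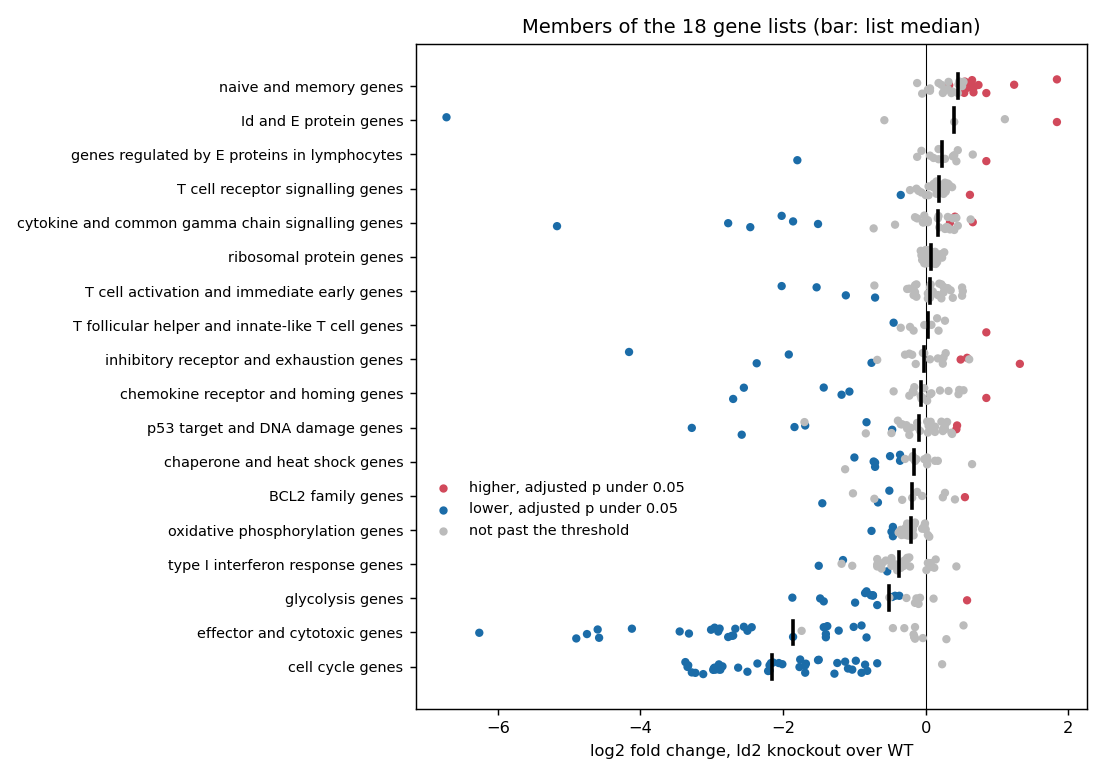
Log2 fold change (knockout over WT) of each tested member of the 18 gene lists, 1 point per gene, coloured by whether it was higher, lower or not past an adjusted p of 0.05, with a bar at the list median. The cell cycle list has its median at -2.15 and the effector list at -1.86, while the naive and memory list has its median at 0.45.

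Markers of other cell types, fixed as lists, were read per library. Of 16 B cell markers 0 passed the threshold by edgeR, DESeq2 or limma and 1 had an unadjusted p under 0.05, with a median of -0.87. Without knockout replicate 2, 14 of them were lower. Cd74 stood at 1460 ± 817 FPKM in WT and 809 ± 751 in knockout. The dendritic cell markers Itgax, Batf3, Zbtb46 and Bst2 fell (4 of 7). Bst2 lost its call without WT replicate 1 (0.0586) or 2 (0.0629) or knockout replicate 1 (0.0842) or 3 (0.119), and without knockout replicate 2 Itgax stood at -4.53 (-3.9 in all libraries) and Zbtb46 at -2.72 (-2.07). Also lower were the plasma cell markers Prdm1 and Jchain (2 of 6). Of 12 fixed gamma delta T cell markers only 3 were tested, none of them a T cell receptor gene. Of these 2 rose, the scavenger receptor genes 5830411N06Rik (5 ± 1.21 to 35.9 ± 10.1 FPKM) and Cd163l1 (7.79 ± 1.84 to 16.1 ± 2.89). The other, Blk, is also in the B cell list, and its levels were 1.01, 5.28 and 1.87 FPKM in knockout replicates 1 to 3. Of 8 CD4 and regulatory T cell markers 3 were higher and 2 lower. These counts were 1 and 1 without knockout replicate 1, and 0 and 1 without knockout replicate 3. Of 7 NK cell markers Gzma fell, and of 2 stromal markers Sparc (log2 fold change -4.25, and -6.41 without knockout replicate 1). Without WT replicate 2, 3 NK cell and 2 myeloid markers fell, and without WT replicate 3, 1 myeloid marker. Without WT replicate 1, 1 NK cell and 1 dendritic cell marker rose, and without knockout replicate 2, 1 gamma delta marker, Blk, fell. Of 11 myeloid markers 0 passed by edgeR or limma, 1 by DESeq2 and 3 at an unadjusted p under 0.05, and no erythroid marker reached the level needed for a test. The camera adjusted p was 0.0103 for B cell, 0.0315 for plasma cell, 0.0446 for dendritic cell and 0.0315 for gamma delta T cell markers, against adjusted p = 0.711, 0.445, 0.379 and 0.492 with an estimated correlation. The B cell call ended without WT replicate 3 (0.124), knockout replicate 1 (0.125) or 3 (0.0768), the plasma cell call without WT replicate 3 (0.0819) or knockout replicate 1 (0.0935), the dendritic cell call without WT replicate 1 (0.0581), WT replicate 3 (0.0868) or knockout replicate 1 (0.124), and the gamma delta call without knockout replicate 2 (0.118). Adjusted over the list alone, 1 dendritic cell marker was higher and 4 lower, 3 plasma cell markers lower, 2 gamma delta markers higher, 3 CD4 T cell markers higher and 2 lower, 1 NK cell marker higher and 3 lower, 1 stromal marker lower, and no B cell or myeloid marker passed. The camera adjusted p was 0.963 for myeloid and for CD4 T cell markers and 0.551 for NK and for stromal markers.

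**Figure D3:**
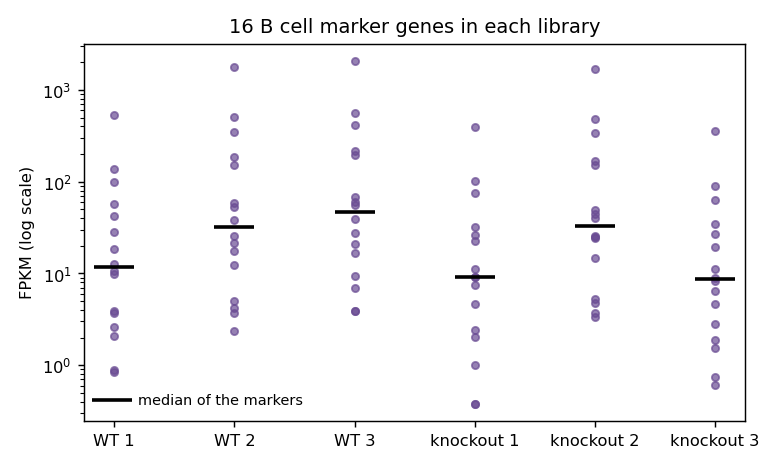
FPKM on a log axis of 16 B cell marker genes in each library, 1 point per gene, with bars at the medians. The medians are 11.7, 32 and 47.4 in WT replicates 1 to 3 and 9.1, 33.1 and 8.6 in knockout replicates 1 to 3.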

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

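Id2 kept its direction and call under the alternatives that gave a value, and effector, cell cycle, naive and memory, glycolysis and oxidative phosphorylation genes kept theirs except with an estimated correlation. Fits with the B cell marker level as a covariate or with only WT replicate 1 and knockout replicates 1 and 3 were chosen after seeing the data, and the lone WT library there is assumed to vary like the others. That library held more Fos (477.53 FPKM against 169.01 and 184.92) and Jun (361.16 against 131.37 and 138.36) than the other WT libraries. The knockout libraries were also above those others, with log2 fold changes without WT replicate 1 of 1.09 for Fos and 0.73 for Jun. In all libraries these were 0.38 and 0.03. List calls gained or lost in the fit with that lone WT library are listed below only to show what changed. No conclusion is drawn from them, since that fit cannot separate genotype from what is particular to the lone WT library. This holds above all for the activation list, of which Fos and Jun are members. Scaling of FPKM by TMM, rescaling to TPM and limma without a trend were planned for tables without counts and not run. The fold change minimum gives no list value. The median log2 fold change of all genes was at most 0.074 under every scaling. Of 79 named genes past the threshold, 54 stayed past it in all 6 fits without 1 library. At depths of 7699181 to 8495123 expected counts, genes with a few counts have wide errors. Why calls or directions changed between fits was not tested.

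With a log2 fold change minimum of 0.5, 424 genes passed, 22 higher and 402 lower. Library weights gave 600 higher genes, and the 3 libraries with low B cell marker levels 631. Without 1 library, the genes past the threshold ranged from 601 to 1562, the higher ones from 84 to 480 and the lower ones from 517 to 1082.

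Other values here are adjusted p of the lists. With an estimated correlation these were 0.343 (effector, cell cycle, naive and memory, glycolysis), 0.379 (oxidative phosphorylation, dendritic cell), 0.629 (interferon), 0.68 (chaperone, T cell receptor), 0.706 (ribosomal), 0.711 (B cell), 0.445 (plasma cell) and 0.492 (gamma delta). Fry ended the calls of interferon (0.147), chaperone (0.126), T cell receptor (0.436), ribosomal (0.179), B cell (0.438) and plasma cell genes (0.0546), made calls of BCL2 family (0.0351), p53 (0.0351) and homing genes (0.0367), and turned CD4 T cell markers (0.487) and cytokine genes (0.448).

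With the covariate, B cell markers turned (0.844), as did H2-Ab1 (log2 fold change 0.01). The covariate is the mean of these markers, H2-Ab1 among them, so the loss of their difference follows from its construction. T cell receptor (0.66), dendritic cell (0.0689), plasma cell (0.121) and ribosomal genes (0.114) lost their call. In the 3 libraries with low B cell marker levels, BCL2 family (0.0403), NK cell (0.0289), activation (3.82e-05), E protein-regulated (0.0195) and p53 genes (0.0436) gained one, plasma cell (0.052) and ribosomal genes (0.0545) lost it, and cytokine genes (0.627), Lyz2 (log2 fold change -0.12) and Xbp1 (-0.05) turned.

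At a minimum of 5 FPKM, CD4 T cell (0.783) and myeloid markers (0.845) turned, dendritic cell (0.221) and plasma cell markers (0.166) lost their call, and E protein-regulated genes gained one (0.0442). With no filter, CD4 T cell (0.766), NK cell and myeloid markers (0.931 each) turned, dendritic cell (0.362) and gamma delta markers (0.0631) lost their call, and homing (0.0375) and E protein-regulated genes (0.0479) gained one. With a pseudocount of 0.1, dendritic cell (0.0552) and gamma delta markers (0.0536) lost theirs. With library weights, CD4 T cell, Id and E protein and activation genes turned (0.99 each), dendritic cell (0.0622) and gamma delta markers (0.1) lost their call and E protein-regulated genes gained one (0.0224). Quantile normalization turned CD4 T cell and myeloid markers (0.994 each) and ended the gamma delta (0.0772) and ribosomal calls (0.0989), the latter also lost without the 50 most abundant genes (0.083).

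Without 1 library in turn, the ranges of results that changed call or direction in at least 1 fit were Id and E protein genes 0.791 to 0.993, genes regulated by E proteins 0.0194 to 0.169, inhibitory receptor genes 0.259 to 0.993, activation genes 0.0581 to 0.931, chaperone genes 0.000308 to 0.667, myeloid cell markers 0.657 to 0.913, dendritic cell markers 0.0225 to 0.124, CD4 T cell markers 0.657 to 0.995, Xbp1 (log2 fold change) -0.03 to 0.06, T cell receptor genes 1.05e-05 to 0.125, ribosomal protein genes 0.0104 to 0.169, B cell markers 2.44e-07 to 0.125, plasma cell markers 0.0084 to 0.0935, gamma delta T cell markers 0.0131 to 0.118.

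With the replicate number as a block (replicate block), 1183 genes passed, and E protein-regulated genes gained a call (0.042). The deviations of same-numbered libraries correlated by 0.118, 0.075 and -0.0303, and 2 of 6 libraries correlated best with their own number. So few libraries cannot show whether a shared number marks a shared litter, day or batch.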

Other observations

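The tests of explanations and the gene families here were all chosen after the results were seen. Of several families outside the fixed lists, with no test of a family as a whole, some members passed the threshold. Of 8 Ly49 receptor (Klra) genes tested, 8 had positive log2 fold changes and 2 passed the threshold by edgeR: Klra13-ps rose from 14.8 ± 2.38 to 39.4 ± 1.09 FPKM (SD, n = 3; 2.62-fold) and Klra23 3.1-fold. Reads of these near-identical genes are hard to divide. All 3 metallothionein genes tested, whose products bind metals, fell: Mt1 from 18.4 ± 0.454 to 1.85 ± 0.849 FPKM, Mt2 with 129 and 3 counts in WT and knockout, and Mt3 with 50 and 1 counts, a ratio of 46.5 (exact 95% counting interval 7.98 to 1870), with a log2 fold change of -5.13, or -4.42 without WT replicate 1 and no counts in knockout without replicate 2. Of 4 Ifitm genes, which encode membrane proteins that restrict viruses, 3 fell: Ifitm1 from 265 ± 145 to 19.3 ± 18.5, Ifitm2 from 148 ± 60.4 to 11.4 ± 9.56 and Ifitm3 from 37.2 ± 8.9 to 5.18 ± 6.45 FPKM. Ifitm3 lost its call without knockout replicate 1 (adjusted p = 0.0556), and without knockout replicate 2 the log2 fold changes were -4.93, -4.63 and -4.57, against -3.83, -3.73 and -2.85. Ifitm10 had a log2 fold change of 0.64 (adjusted p = 0.114).

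Of 4 Serpinb genes 3 fell, among them Serpinb9, which encodes an inhibitor of granzyme B, from 129 ± 6.51 to 18.4 ± 8.51 FPKM, and Serpinb6b from 86.7 ± 12.6 to 27.3 ± 6.61. Serpinb6a, also counted, fell 1.34-fold and barely passed (adjusted p = 0.0499, edgeR). Among beta tubulin genes Tubb2a rose (2.81-fold) and Tubb3 fell (6.77-fold). The rise of Tubb2b (2.72-fold) and the falls of Tubb4b (2.13-fold) and Tubb6 (2.23-fold) lost their calls in 5, 3 and 6 of the 6 fits of 5 libraries. Of 10 glutathione S-transferase genes 3 fell: Gsto1 (2.24-fold), Gstt1 (4.35 ± 1.44 to 0.16 ± 0.277 FPKM, with no counts in knockout but for replicate 1) and Gstm5, which had 50 counts in WT and 0 in knockout, at least 15.5-fold lower against a floor of 3 counts over the group. Across 5 other scalings and tests, no member of the Klra, metallothionein, Ifitm, Serpinb or beta tubulin families changed sign, and of the glutathione S-transferases Gstz1 and Gstp3, both near 0, did.

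The real grouping gave 1297 genes past the threshold and the highest of the other 9 splits of the 6 libraries 40. For lists, the real grouping gave 13 camera calls, the highest other split 12 and the rest 4 to 8. Every grouping that mixes the genotypes thus also gave list calls, and 1 gave nearly as many. For genes as for lists, 1 of 10 splits, the real one, reached the real value, and 10 splits are too few for a share under 0.05. The split with 40 genes parts WT replicate 1 and knockout replicates 1 and 3 from the rest, as the B cell marker level does.

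The fall of effector and cell cycle genes covered 69 members with a median log2 fold change of -2.44. Unequal B cell RNA is argued against as the whole source. With the B cell marker level as a covariate, the median was -2.15 over all 39 effector genes tested and -1.91 over all 42 cell cycle genes. Without the covariate these medians were -1.86 and -2.15. The 69 had a median of -2.29 and an upper quartile of -1.43 with the covariate, and all passed the threshold. They had been picked as lower in the same libraries, so their values alone decide little. The weight of a few abundant genes is also argued against, since the 50 most abundant genes took 15.5% to 17.3% of the counts of each library. The share left to other genes thus differed between the groups by -0.01 on the log2 scale (-0.031 from the highest WT to the lowest knockout library). A smaller share of effector and dividing cells among the sorted cells may account for it and cannot be told apart in bulk libraries from lower expression per cell. The 69 members fell by unequal amounts (interquartile range 1.53), which remaining cells that express some of them could also give. That range leaves out the members not past the threshold, such as Prf1 and E2f1.

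The 12 largest rises had a median of 1.73. Loss of effector cells may have raised the share of other T cells, and the 30 naive and memory genes outside the 12 had a median of 0.41 and an upper quartile of 0.57. Because the 12 were picked as the largest rises, and Id3 stands in both groups and was removed, that difference does not exclude it. A change in a subset that makes these transcripts, or in expression per cell after loss of Id2, stays open as a hypothesis and was not tested.

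Of 6 genes annotated as small nuclear RNAs, a group picked after the results, 3 rose in the knockout libraries: Rn7sk, Rnu2-10 and Rnu3b1. Without knockout replicate 3 or WT replicate 3, Rnu2-10 (adjusted p = 0.053 and 0.0548) and Rnu3b1 (0.0787 and 0.0573) lost their calls. The median of the 6 was 0.92 (quartiles 0.39 and 1.23). With the B cell marker level as a covariate the median was 0.86 (lower quartile 0.42), 3 passed the threshold and Rnu3b4 stood at -0.16. The group was picked as higher in the same libraries, so these values alone decide little about unequal B cell RNA. Carry-over of more RNA without a poly(A) tail may be the source if the libraries were poly(A)-selected. The standard Illumina protocol named for these libraries does not settle that. The values are also divided. Of 16 small nucleolar RNAs 15 had positive log2 fold changes, with a median of 0.57 and a lower quartile of 0.43. Their upper quartile of 0.64 stayed below the 0.92 of the small nuclear RNAs. Of the 16, 0 passed the threshold by edgeR or DESeq2, 3 by limma, and 2 had an unadjusted p under 0.05. The first criterion used, that they must rise as far, argued against carry-over, and a second one, that they must only rise, argued for it. Since the second was set after the first had been read, neither decides. Rnu3b1 is a U3 gene, which the annotation counts as small nuclear although U3 is nucleolar.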
